A study of Sinorhizobium meliloti with 16 samples.

How the data were processed

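Sinorhizobium meliloti Sm1021, a soil bacterium that forms nitrogen-fixing nodules on legumes, was grown free-living to mid-log phase. Per the labels, 3 strains each carried 1 cold shock protein (CspA2, CspA4 or CspA5) fused to green fluorescent protein (GFP), and the wild type without a fusion served as the control. Cold shock proteins are small proteins that bind single-stranded RNA. Lysates were passed over GFP-Trap beads, agarose that carries a GFP-binding antibody fragment, without crosslinking (a native immunoprecipitation). RNA was extracted with Trizol, and stranded total RNA libraries were made, per the labels' protocols. The labels list 16 samples: an input and a bound fraction of each of the 4 strains, each with numbers 1 and 2.

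The table analysed here has 8 columns, which is 1 per strain and number. Its headers give the strain and the number and do not say whether a column is the input or the bound fraction. The columns were therefore used as libraries of a strain, and all comparisons are between strains. If the columns are bound fractions, a difference between strains can come from the immunoprecipitation, from the starting RNA or from both, because no column was used as input. Enrichment over input, planned before the data were examined as the main comparison, was not analysed here. Each tagged strain against the untagged strain with no reference to input, the nearest comparison written down beforehand, took its place after the table was seen, and the tagged strains were also compared with each other. Nothing in the labels says whether numbers 1 and 2 were separate cultures, so p-values measure the spread between these libraries, which may be partly technical.

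The deposited values are whole-number read counts per gene, not normalised, with 1 row per locus tag. Per the submitters' processing notes, TopHat, SAMtools and edgeR were used by the authors; their versions and roles, the counting program, the genome build, the annotation and the use of strand are not given in the sources used here. Reads of overlapping genes or near-identical copies can be split between rows in ways that were not checked. The deposited table holds 1937 locus tags, with a lowest count of 1, a lowest row total of 50 and 0 values at 0. An RNA without a read in 1 of the 8 libraries therefore has no row, and such an RNA could not be tested. Library totals over these rows ran from 163673 to 1014273 counts; as the table may not hold every gene, these totals may lie below the full depth of the libraries.

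Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM scaling, 1 mean per strain, Benjamini-Hochberg adjustment over the genes tested, threshold 0.05). All 8 libraries entered 1 fit, which left 4 residual degrees of freedom. The low-count filter of edgeR (filterByExpr) left 1934 genes and removed 3. Standard errors of log2 fold changes were taken as the fold change divided by the square root of its F value, and 95% intervals from the t distribution with the fit's degrees of freedom. Levels are CPM, a gene's counts relative to the library total scaled by its TMM factor, as mean ± SD of 2 libraries. Intervals of single-library shares are exact (Clopper-Pearson, 95%) and cover counting error only; no bound lay over 0.23 percentage points from a share of SMc07123 or over 0.17 points from a share of a replicon. The test was checked on simulated counts for the 1934 genes with 200 changed genes per comparison. All genes raised 8-fold and 16-fold were recovered (100%) in each comparison with the untagged strain. Of genes raised 4-fold, 52% were recovered for CspA2-GFP, 88% for CspA4-GFP and 52% for CspA5-GFP, and of those raised 2-fold 0%, 16% and 4%. Of genes lowered 4-fold, 52%, 44% and 52% were recovered, and of those lowered 8-fold 80%, 96% and 64%. Among the unchanged genes 0, 8 and 3 were called. The counts were drawn from the spread fitted to the data, without outlying libraries. The simulated comparisons had 117, 148 and 119 calls, against 17, 8 and 20 in the data, and more calls loosen the adjustment. Recovery in the data can thus be lower. SMa1545, chosen after its values were seen, had a log2 fold change of 3.86 in CspA5-GFP without passing (edgeR adjusted p = 0.15). Its CspA5-GFP libraries held 880 and 59 CPM.

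Locus tags are given as the table writes them. None of them (0 of 1937) matched the gene table at hand, which describes another strain of the species, so they carry no gene names, coordinates or functions here. The 25 gene lists fixed by gene symbol before the data were examined could therefore not be tested, nor could the csp genes be read. The 3 lists fixed by prefix were tested: SMc for the chromosome, SMa for the megaplasmid pSymA and SMb for the megaplasmid pSymB. Set tests used camera with a preset correlation of 0.01, camera with an estimated correlation, and fry (limma 3.58.1), adjusted over 9 tests.

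The rule for named genes fixed before the data were examined was written for ratios of bound to input and for more genes per comparison, and it was adapted to this table after the columns were seen. As used, it takes genes past the threshold with a mean of at least 20 counts per library and both libraries of one strain beyond both of the other, and names the 2 with the largest fold change in each direction, because the locus tags carry no names. For the same reason genes that did not pass and members of the fixed lists are not named by rule. Other tags are named only where the text says that they were chosen after their values were seen.

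The alternatives were RLE scaling, scaling by library size alone, leaving out the 17 genes that take over 1% of any library, and no low-count filter. Further alternatives were DESeq2 1.42.0, the number as a block, only the 2 strains compared, and leaving out 1 library. Each library of the 2 strains compared was left out in turn. Fits without a library of another strain are not part of the counts given. Thinning every library to 163673 counts was added after the data were seen. Overlaps between comparisons that share the untagged libraries were set against 100 simulations of unchanged strains, in which the untagged libraries were simulated too. No check of GC content or gene length was made, because the locus tags matched no annotation.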

Results

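The series, a native immunoprecipitation followed by RNA sequencing, concerns the RNAs recovered with 3 cold shock proteins of Sinorhizobium meliloti. The table holds read counts for 1937 locus tags in 8 libraries, 2 each from the untagged wild type and from strains carrying CspA2-GFP, CspA4-GFP or CspA5-GFP. The column headers name the strain and not the fraction, so the values below compare strains. The untagged libraries held 163673 and 198821 counts. The CspA2-GFP libraries held 1014273 and 662518 counts, the CspA4-GFP libraries 705444 and 782821, and the CspA5-GFP libraries 438302 and 288883. Libraries of the same strain correlated across genes, which are not independent replicates, with a Spearman rho between 0.806 (CspA4-GFP) and 0.881 (CspA2-GFP). Libraries of different strains correlated between 0.726 and 0.883. The counts of both libraries of a strain differed by more than sampling noise in every strain, with a chi-square per degree of freedom of 2.05 in the untagged strain, 39.6 in CspA2-GFP, 50.9 in CspA4-GFP and 26.0 in CspA5-GFP. This statistic grows with depth, so by itself it does not rank the strains by reproducibility. It shows that no pair agreed within counting noise. Whether depth accounts for the gap between 2.05 and the values of the tagged strains was not tested. The fit pooled the spread of all strains, so its p-values do not carry a difference in spread between strains.

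A few RNAs took much of each library. The chromosomal locus tag SMc07123 held 35.3% (exact 95% interval 35.11 to 35.58) and 33.1% (32.87 to 33.29) of the counts in the untagged libraries. Its share was 7.14% and 6.51% in the CspA2-GFP libraries, 9.64% and 6.13% in CspA4-GFP, and 15.4% and 25.3% in CspA5-GFP. By replicon, the chromosome (1386 locus tags) held between 74.6% and 87.1% of the counts of a library. The megaplasmid pSymA, which carries the nodulation genes, has 213 locus tags in the table. They held 13.2% and 9.34% of the CspA2-GFP libraries, 5.57% and 8.40% of CspA4-GFP, 4.82% and 3.86% of CspA5-GFP, and 3.45% and 3.37% of the untagged libraries. Without SMa6570, a locus tag singled out after its values were seen, the pSymA share was 4.53% and 4.89% in CspA2-GFP, 4.22% and 4.93% in CspA4-GFP, 4.19% and 2.89% in CspA5-GFP, and 3.04% and 2.91% in the untagged libraries. Shares are relative, so the lower share of SMc07123 in the tagged strains raises the shares of all other genes. The pSymA shares were not corrected for this, so they do not by themselves show more pSymA RNA. With 2 libraries against 2, an exact two-sided permutation test of such shares cannot give a p below 0.333, and none was run.

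The comparison of CspA2-GFP with the untagged strain asks which RNAs are more abundant in the libraries of the tagged strain. SMc06496 and SMc02855, both chromosomal, rose most among the genes that passed. SMc06496 was at 986 ± 171 CPM in the untagged strain and 17300 ± 7960 CPM in CspA2-GFP (SD, n = 2), a log2 fold change of 4.14 (SE 0.50, edgeR adjusted p = 0.0041). SMc02855 went from 1070 ± 288 to 18100 ± 4540 CPM, a log2 fold change of 4.08 (SE 0.52, edgeR adjusted p = 0.0048). In all, 15 of 1934 genes were higher, with a median log2 fold change of 3.02, and 2 were lower. The genes that rose comprised 11 of 1383 on the chromosome, 2 of 213 on pSymA and 2 of 338 on pSymB. Adjusted over the list alone, the numbers higher were 11, 3 and 1. SMc07123 fell from 371000 ± 12000 to 66000 ± 13600 CPM, a log2 fold change of -2.49 (SE 0.48, edgeR adjusted p = 0.042). SMc01969, chosen after its values were seen because only 2 genes fell, dropped from 108 ± 4.80 to 15.9 ± 3.34 CPM on a mean of 19 counts per library, with a log2 fold change of -2.75 (SE 0.46, edgeR adjusted p = 0.017). With either untagged library left out 0 genes passed in either direction, with the log2 fold change of SMc06496 at 3.97 and 4.32; 3 were higher and 0 lower without CspA2-GFP library 1, where SMc02855 no longer passed (log2 fold change 3.80, edgeR adjusted p = 0.052), and 11 and 0 without library 2. The log2 fold change of SMc07123 was -2.29 to -2.71 with 1 library left out. With the number as a block it was -2.49 and did not pass (edgeR adjusted p = 0.080). DESeq2 called 26 genes higher, and a fit of only these 2 strains 44 higher and 11 lower.

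Against the untagged strain, CspA4-GFP was higher in 8 genes, and 6 of them were also higher in CspA2-GFP. SMb20592, on pSymB, rose from 508 ± 98.3 CPM in the untagged strain to 4880 ± 1850 CPM, a log2 fold change of 3.26 (SE 0.51, edgeR adjusted p = 0.027). SMc02855 reached 8990 ± 3650 CPM, a log2 fold change of 3.07 (SE 0.50, edgeR adjusted p = 0.027). The 8 genes had a median log2 fold change of 2.94, and 0 genes were lower. In either direction 174 of the 1934 genes had an unadjusted p under 0.05 in edgeR. A share of 0.05 of the genes is expected there without any change. DESeq2 called 17 higher and 1 lower. Of the 8 genes, 4 were chromosomal, 2 on pSymA and 2 on pSymB; adjusted over the list alone, 3, 2 and 3 were higher. SMc07123 was at 67200 ± 22200 CPM, with a log2 fold change of -2.46 (SE 0.48) that did not pass (edgeR adjusted p = 0.073). No gene passed with either untagged library left out, with the log2 fold change of SMb20592 at 3.08 and 3.47 and that of SMc02855 at 2.82 and 3.38; without CspA4-GFP library 2 there were 3 higher and 2 lower, and SMb20592 (2.81, edgeR adjusted p = 0.054) and SMc02855 (2.59, edgeR adjusted p = 0.060) no longer passed. Scaling by library size alone gave 20 higher and 1 lower, and leaving out the 17 genes over 1% of any library, SMc06496 and SMc02855 among them, gave 3 higher.

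CspA5-GFP was higher than the untagged strain in 20 genes, 0 of which passed in CspA2-GFP or CspA4-GFP. Over the untagged strain, 13 of them lay above 0 in CspA2-GFP (median log2 fold change 0.57) and 18 in CspA4-GFP (median 0.31). They were picked for high values over the same untagged libraries, which favours values above 0. SMb20463, on pSymB, rose from 233 ± 51.8 CPM in the untagged strain to 55200 ± 28100 CPM in CspA5-GFP, a log2 fold change of 7.88 (SE 0.83, edgeR adjusted p = 0.00069) and the largest of any gene that passed in a comparison with the untagged strain. It took counts of 31052 and 8382 in the CspA5-GFP libraries and of 30 and 49 in the untagged libraries. In CspA2-GFP it was at 994 ± 569 CPM, a log2 fold change of 2.09 (95% interval 0.62 to 3.55) that did not pass (edgeR adjusted p = 0.27). The chromosomal SMc01068 rose from 38.9 ± 0.548 to 2170 ± 966 CPM, a log2 fold change of 5.79 (SE 0.46, edgeR adjusted p = 0.00019). Of the 20 genes, 16 were on the chromosome, 4 on pSymB and 0 on pSymA, with the same numbers adjusted over the list alone. Their median log2 fold change was 4.08. No gene was lower in edgeR or DESeq2. In either direction 204 of the 1934 genes had an unadjusted p under 0.05 in edgeR, where a share of 0.05 is expected without any change. SMc07123 was at 236000 ± 102000 CPM, with a log2 fold change of -0.65 (SE 0.46, edgeR adjusted p = 0.67). With either untagged library left out 7 of the 20 genes remained. Without CspA5-GFP library 2, 87 genes were higher, including all 20, and 1 was lower, and DESeq2 called 46 higher.

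**Figure D1:**
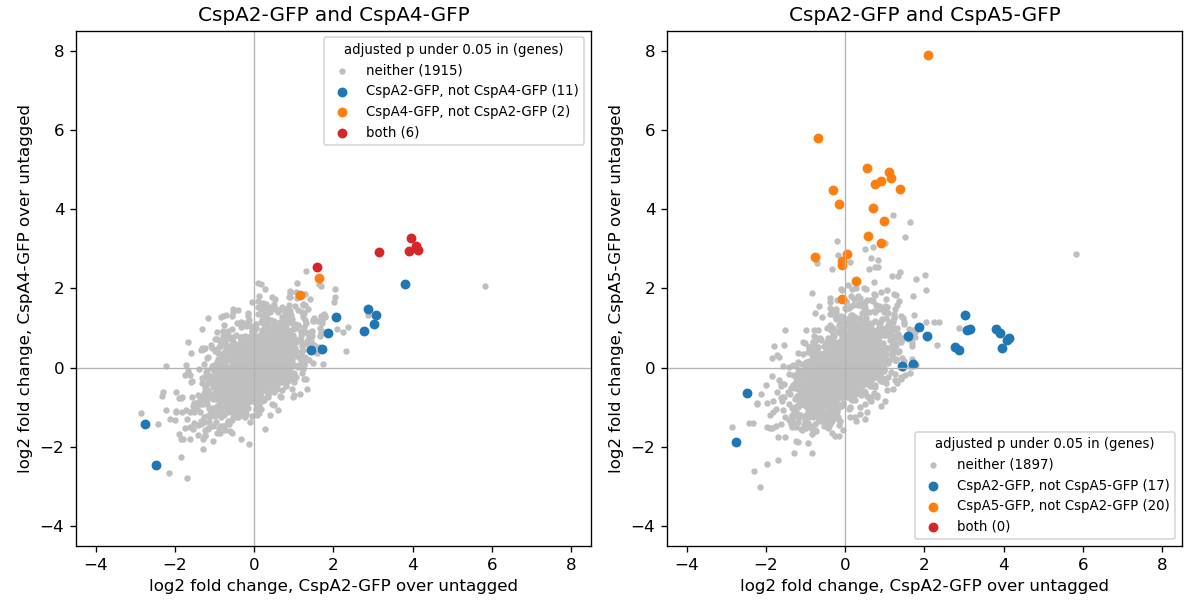
Log2 fold change over the untagged strain of each of the 1934 genes tested, CspA4-GFP (left) or CspA5-GFP (right) on the vertical axis against CspA2-GFP on the horizontal axis, coloured by which comparison passed edgeR's adjusted p of 0.05. In the left panel 6 genes passed in both comparisons and lie at the upper right; in the right panel 0 genes passed in both, and the 20 genes high with CspA5-GFP lie between -0.77 and 2.09 on the CspA2-GFP axis.

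The overlap of these calls addresses whether the same RNAs were higher with each of the 3 proteins. CspA2-GFP and CspA4-GFP shared 6 of the genes higher than in the untagged strain, SMc06496, SMc02855 and SMb20592 among them. Independent lists of these sizes would share 0.062 genes. In 100 simulations of unchanged strains, with the untagged libraries simulated too, 0.01 genes were shared on average and 1 at most. Unchanged strains are expected to give almost no calls, so this low overlap was set in advance. It does not show what shared untagged libraries would give lists of 15 and 8 genes. CspA5-GFP shared 0 higher genes with CspA2-GFP and 0 with CspA4-GFP, where independent lists would share 0.16 and 0.083. All 15 genes high with CspA2-GFP lay above 0 in CspA5-GFP against the same untagged libraries (median log2 fold change 0.79), as did all 8 genes high with CspA4-GFP (median 0.77). They were picked for high values over those libraries, which favours values above 0 without any change in CspA5-GFP. Across all genes, which are not independent replicates, the fold changes of CspA2-GFP and CspA4-GFP correlated with r = 0.615, against 0.647 in the simulations; their covariance was 0.321 against 0.255. For CspA2-GFP and CspA5-GFP r was 0.495 against 0.614 and the covariance 0.317 against 0.254. For CspA4-GFP and CspA5-GFP r was 0.378 against 0.616 and the covariance 0.226 against 0.255. The controls were not split, as each part would hold 1 library, so part of any excess may come from the shared libraries. Comparisons with no library in common were therefore set side by side. Of the 15 genes higher in CspA2-GFP than in the untagged strain, 6 were also among the 13 higher in CspA4-GFP than in CspA5-GFP, where independent lists would share 0.10. Of the 8 genes higher in CspA4-GFP than in the untagged strain, 5 were among the 13 higher in CspA2-GFP than in CspA5-GFP, where independent lists would share 0.054. Across all genes these pairs of comparisons correlated with r = 0.0051 and 0.167. At an adjusted p of 0.01 CspA2-GFP and CspA4-GFP shared 1 gene, and with either untagged library left out neither strain had a higher gene to share.

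Direct comparison of CspA2-GFP with CspA4-GFP found 0 genes that differed in edgeR and 0 in DESeq2. In edgeR 193 of the 1934 genes had an unadjusted p under 0.05, where a share of 0.05 is expected without any change. For SMc06496 the log2 fold change of CspA2-GFP over CspA4-GFP was 1.17 (95% interval 0.19 to 2.15, edgeR adjusted p = 0.46). For SMb20592 it was 0.69 (-0.32 to 1.69), and for SMc07123 it was -0.03 (-1.03 to 0.98). The intervals of SMb20592 and SMc07123 cover differences in both directions, and equal levels were not shown. The 15 genes higher in CspA2-GFP than in the untagged strain had a median log2 fold change of 1.01 over CspA4-GFP, and 14 of them lay above 0; the 8 genes higher in CspA4-GFP had a median of 0.45 in the same contrast, and 5 lay above 0. Each list was picked on libraries that this contrast uses again, which favours its own strain. Without CspA4-GFP library 2, 4 genes were higher and 22 lower in CspA2-GFP, and without CspA2-GFP library 2, 1 was higher.

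CspA5-GFP differed from both other tagged strains. Against CspA5-GFP, 13 genes were higher and 25 lower in CspA2-GFP, and 13 were higher and 25 lower in CspA4-GFP. SMb20592 and SMc02855 were among the highest in both. SMb20592 was at 7850 ± 2540 CPM in CspA2-GFP and 723 ± 490 CPM in CspA5-GFP, a log2 fold change of 3.45 (SE 0.50, edgeR adjusted p = 0.0047), and that of CspA4-GFP over CspA5-GFP was 2.76 (SE 0.49, edgeR adjusted p = 0.015). SMc01068 and SMb20463 were the lowest in both. The log2 fold change of SMc01068 was -6.49 (SE 0.44, edgeR adjusted p = 4.36e-05) for CspA2-GFP and -5.47 (SE 0.42, edgeR adjusted p = 0.00013) for CspA4-GFP. That of SMb20463 was -5.79 (SE 0.74, edgeR adjusted p = 0.0022) and -6.91 (SE 0.78, edgeR adjusted p = 0.0011). Of the 20 genes higher in CspA5-GFP than in the untagged strain, 19 were lower in CspA2-GFP than in CspA5-GFP and 19 were lower in CspA4-GFP. Of the 15 genes higher in CspA2-GFP than in the untagged strain, 11 were higher than in CspA5-GFP. These genes were picked on libraries that the contrasts use again, so the counts are not independent evidence. By replicon, CspA2-GFP was higher than CspA5-GFP in 9 genes of the chromosome, 3 of pSymA and 1 of pSymB and lower in 20, 1 and 4; adjusted over the list alone, the numbers were 10, 4 and 1 higher and 21, 1 and 4 lower. CspA4-GFP was higher in 7, 2 and 4 and lower in 21, 0 and 4, and adjusted over the list alone in 7, 1 and 4 and in 21, 0 and 4. DESeq2 called 20 higher and 44 lower in CspA2-GFP and 23 higher and 51 lower in CspA4-GFP; in fits of 2 strains alone, 0 genes were higher in CspA2-GFP or CspA4-GFP than in CspA5-GFP and 8 and 14 were lower, with the log2 fold change of SMb20592 at 3.44 and 2.76 and that of SMc02855 at 3.38 and 2.38, while library size alone gave 18 higher and 23 lower in CspA2-GFP and 37 higher and 22 lower in CspA4-GFP. For CspA2-GFP, leaving out its library 1 gave 1 higher and 11 lower, its library 2 gave 14 lower and CspA5-GFP library 2 gave 86 lower; for CspA4-GFP, leaving out its library 1 gave 13 lower, its library 2 gave 47 higher, CspA5-GFP library 1 gave 6 higher and CspA5-GFP library 2 gave 99 lower.

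**Figure D2:**
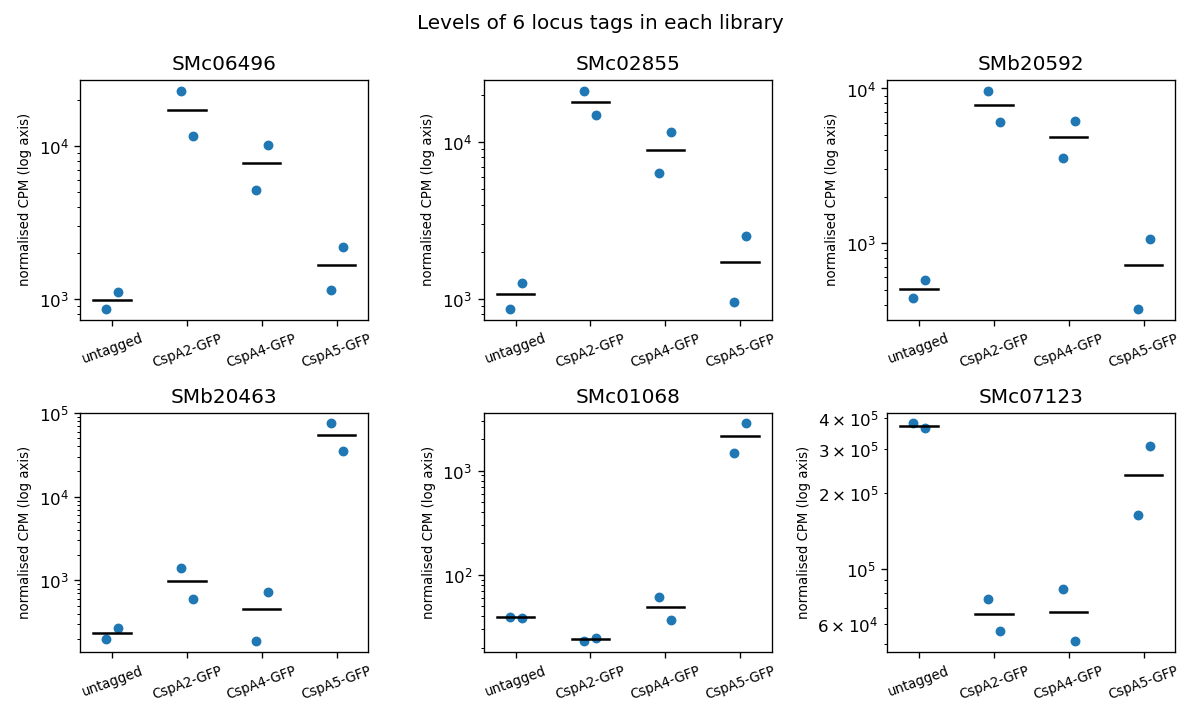
Normalised CPM (log axis) of 6 locus tags in the 8 libraries, by strain; points are libraries and bars are means of 2. SMc06496, SMc02855 and SMb20592 are highest in the CspA2-GFP and CspA4-GFP libraries, SMb20463 and SMc01068 in the CspA5-GFP libraries, and SMc07123 in the untagged libraries.

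As sets, the genes of the 3 replicons did not pass camera, which sets them against the other genes, in any comparison with the untagged strain. The medians of the log2 fold changes lay between -0.04 (pSymB, CspA2-GFP) and 0.14 (pSymA, CspA5-GFP). The camera adjusted p was between 0.891 and 0.937 with the preset correlation and between 0.718 and 0.949 with an estimated one. The directional fry test, which asks whether a set moved one way and compares it with no other genes, gave adjusted p between 0.487 and 0.99. In CspA2-GFP pSymA was up by camera with the preset correlation and down with the estimated one. In CspA4-GFP the median of pSymA (-0.0024) and its mean (0.033) had opposite signs, as did those of pSymB (-0.017 and 0.036), and so did those of pSymB in CspA5-GFP (-0.036 and 0.019); in these last 2 sets camera pointed down and fry up. For a change of members in either direction, again without other genes, fry gave limma adjusted p of 0.0016, 0.0016 and 0.0072 for chromosome, pSymA and pSymB in CspA2-GFP, 0.026, 0.00059 and 0.0017 in CspA4-GFP, and 0.023, 0.13 and 0.026 in CspA5-GFP. The 3 sets together hold all genes tested, and this test was not run on all genes at once. These values therefore speak to changes among members and do not set a replicon apart.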

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

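The results below were singled out because tagged strains differed by a direct test, the contrast of 2 tagged strains. It compares levels without input and does not separate recovery from the starting RNA. The tests of shared untagged libraries, of library depth, of CspA5-GFP library 1 and of neighbouring locus tags were chosen after the result was seen, as were the locus tags named for the last.

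CspA2-GFP differed from CspA5-GFP in 13 genes that were higher and 25 that were lower, and CspA4-GFP differed from CspA5-GFP in 13 higher and 25 lower. In edgeR, the log2 fold changes of CspA2-GFP and CspA4-GFP over CspA5-GFP were 3.38 and 2.21 for SMc06496, 3.39 and 2.38 for SMc02855, and 3.45 and 2.76 for SMb20592. They were -5.79 and -6.91 for SMb20463 and -6.49 and -5.47 for SMc01068. Without CspA2-GFP library 1 the first split was 1 higher and 11 lower, without CspA2-GFP library 2 14 were lower, and without CspA5-GFP library 2 86 were lower. The second had 13 lower without CspA4-GFP library 1, 47 higher without CspA4-GFP library 2, 6 higher without CspA5-GFP library 1 and 99 lower without CspA5-GFP library 2. Groups of 2 libraries are too small for a test of single outlying samples or for a count of other splits of the libraries.

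The first pattern is that CspA2-GFP and CspA4-GFP shared 6 higher genes. The untagged libraries common to both comparisons are not its whole cause: the 15 genes high with CspA2-GFP had a median log2 fold change of 1.03 in CspA4-GFP over CspA5-GFP, which shares no library with the first comparison, and 95% of random lists matched on expression lay between -0.402 and 0.276. After thinning all libraries to the smallest total, in a fit of 1495 genes, 6 of the 6 genes still passed in both strains. Unequal counting noise was thus not the whole cause. Thinning leaves the expected fold changes as they were. It cannot show whether another trait of the deeper libraries played a part. Under RLE or library size alone the lowest log2 fold change of the 6 genes was 1.58. Neither setting moved the strains towards the untagged strain, so this could not have come out otherwise. A scale factor moves all genes alike. In the main fit the 6 genes lay at 1.58 to 4.13 in CspA2-GFP and 2.53 to 3.26 in CspA4-GFP. The medians of all genes were 0.037 and 0.026, and 0.22 and 0.37 with library size alone. These values argue against scaling as the reason why the 6 genes stood above the others. A shift common to all genes stays open. Recovery with both proteins is a hypothesis that stays open, as does a difference in the starting RNA of both strains, because the fraction of the columns is not named and no input was analysed here.

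The second pattern is the set of 20 genes high with CspA5-GFP. As these genes were picked on both CspA5-GFP libraries, library 1 as a lone source was tested on a list picked without library 2. The list held 87 genes higher than in the untagged strain, all of the 20 among them. In library 2 their median log2 fold change was 0.285 over CspA2-GFP and 0.342 over CspA4-GFP. For random lists matched on expression, 95% lay between -0.122 and 0.0907 and between -0.116 and 0.131. Of the 87 genes, 57 lay above 0 over CspA2-GFP and 63 over CspA4-GFP. The medians describe the list as a set and do not show that its genes outside the 20 rose in library 2. In the edgeR fit without library 1, which tests all genes on library 2, 21 genes were higher than in the untagged strain and 18 of the 20 were among them, which argues against library 1 as the source of those 18; for the other 2 it stays open. A candidate explanation for part of the set is that neighbouring genes rose together, as on a shared transcript: of the 20 genes, 2 pairs followed each other in number in the table (SMb20463 with SMb20464, SMc00655 with SMc00657), where the upper bound of the central 95% of 10000 random lists of the same replicons was 1 and a share of 0.0174 of the lists held as many. Locus tag numbers stand in here for genome order, which was not checked, and a change in the starting RNA of the CspA5-GFP strain is untested.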

How the results depend on the processing

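Thinning was added after the data were seen. All 171 alternative values of the named genes kept their direction, 147 kept their side of the threshold and 24 no longer passed: 4 in fits of only 2 strains, 1 under the block and the rest with 1 library left out. Genes were named for large fold changes with both libraries of one strain beyond both of the other. That they kept their direction was thus largely set in advance. Where no construction is named, the cause was not tested. DESeq2 called more genes: 26 higher in CspA2-GFP, 17 higher and 1 lower in CspA4-GFP and 46 higher in CspA5-GFP than in the untagged strain, 20 higher and 44 lower in CspA2-GFP than in CspA5-GFP, and 23 higher and 51 lower in CspA4-GFP than in CspA5-GFP. With only the 2 strains compared, 44 genes were higher and 11 lower in CspA2-GFP than in the untagged strain, 0 higher and 8 lower in CspA2-GFP than in CspA5-GFP, and 0 higher and 14 lower in CspA4-GFP than in CspA5-GFP. Library size alone gave CspA4-GFP 20 higher and 1 lower against the untagged strain and 37 higher against CspA5-GFP; it put the median log2 fold change of all genes at 0.22 for CspA2-GFP and 0.37 for CspA4-GFP over the untagged strain, 0.24 and 0.41 over CspA5-GFP, and -0.16 for CspA2-GFP over CspA4-GFP. Leaving out genes over 1% of a library removed SMc06496 and SMc02855 from the test and gave 3 higher in CspA4-GFP and 1 lower in CspA2-GFP; thinning also gave 1 lower there. At an adjusted p of 0.01, CspA2-GFP and CspA4-GFP shared 1 gene. With 1 library left out, a lone library is assumed to vary like the others. The counts against the untagged strain then ranged from 0 to 11 higher and 0 to 0 lower in CspA2-GFP, 0 to 6 and 0 to 2 in CspA4-GFP, and 7 to 87 and 0 to 1 in CspA5-GFP. CspA2-GFP against CspA4-GFP gave 0 to 4 higher and 0 to 22 lower, CspA2-GFP against CspA5-GFP 1 to 17 and 11 to 86, and CspA4-GFP against CspA5-GFP 6 to 47 and 13 to 99. The lowest numbers of higher genes against the untagged strain came without either untagged library, the highest for CspA5-GFP without its library 2. With the number as a replicate block, CspA4-GFP had 6 higher genes, CspA2-GFP 15 and CspA5-GFP 20; it moved no count by over 1.5 times, and of the named calls it changed that of SMc07123 in CspA2-GFP alone (edgeR adjusted p = 0.0803, where the adjusted p over its alternatives ran from 2.18e-07 with DESeq2 to 0.381 in edgeR without CspA2-GFP library 2). Deviations of same-numbered libraries correlated between -0.018 and 0.095 over the 6 pairs of strains, so no pairing by number was seen. Counting noise at low counts pulls such correlations towards 0, so a batch shared by number is not excluded. Not run: comparisons with input and between inputs, a block per strain and number (each is 1 column), and the gene lists by symbol. The untagged libraries were the smallest, at 163673 and 198821 counts with medians of 11 and 13 counts per gene. Thinning every library to 163673 counts gave 15, 9 and 23 higher genes in CspA2-GFP, CspA4-GFP and CspA5-GFP. The low-count filter then left 1495 genes instead of 1934, so the adjustment was over fewer genes. These counts therefore do not show that depth had no effect on the calls. What a greater depth of the untagged libraries would detect was not tested.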

Other observations

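The locus tag numbers of this table fall into a main range and a block of high numbers (from 5000 for SMc and SMa and from 22000 for SMb), chosen after the data were seen. The block holds 94 of the 1934 genes tested (4.86%). Of the 15 genes higher in CspA2-GFP than in the untagged strain 8 lay in the block (odds ratio 24.2, Fisher's exact test, two-sided, p = 1.13e-07), of the 8 in CspA4-GFP 4 (odds ratio 20.3, Fisher's exact test, p = 0.000316), and of the 20 in CspA5-GFP 0 (Fisher's exact test, p = 0.621). The 4 block genes of CspA4-GFP were all among the 8 of CspA2-GFP, called over the same untagged libraries. The test for CspA4-GFP is therefore not a separate observation. These tests are across genes, which are not independent replicates, and what the block's locus tags encode was not known here.

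Block genes had a higher median of the mean count per library (61.5 against 44), so abundance may give them more calls. Over CspA2-GFP and CspA4-GFP together, 8 of 17 genes lay in the block, where random lists matched on expression held a median of 2, the upper bound of their central 95% was 5 and a share of 4e-04 held as many, which argues against abundance as the whole cause. The count of 0 in CspA5-GFP is within chance of the block's share of all genes, and a difference between the strains in this count was not tested.

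SMc07201, chosen after its values were seen, had the largest fitted log2 fold change of CspA2-GFP over the untagged strain (5.83) without passing (edgeR adjusted p = 0.13). It stood at 7030 CPM in CspA2-GFP library 1 and at 132 CPM in library 2, against 65.5 and 60.6 CPM in the untagged libraries. The other libraries held 241 to 675 CPM.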
